A study of Mus musculus with 16 samples.

How the data were processed

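ATAC-seq was analysed in 16 libraries of mouse prostate organoids, 4 each of Control with DHT, Control with EtOH, SPOPmut with DHT and SPOPmut with EtOH (10 nM DHT or the solvent for 24 h). All libraries carry the label sgNT, whose meaning was not needed here. Per the submitters' processing notes, reads were aligned to the mouse genome mm10 with Bowtie2 2.3.4.1, handled with SAMtools 1.8, and peaks were called with Genrich (version not stated), here in each library on its own. The -log10 p at each peak summit is the authors' own value from the peak caller and depends on the depth of the library. The signal of each peak, the area under the caller's significance track, was deposited as the authors computed it, and its smallest value in each list is just over 200. The score was deposited as a whole number with an upper limit of 1000, and no q value was given. These values were used only to rank or filter peaks within a list. The lists hold no read counts, so sequencing depth is unknown and list length is given in its place. Signal tracks pooled over the replicates of a group were not used here.

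Peaks of the 16 lists that overlapped by at least 1 bp were merged into 86616 regions (median width of those tested 667 bp), and a region counted as called in a library when a peak of its list overlapped it. The 6264 regions called in 1 library were set aside, which left 80352 tested. Genes came from a table of gene starts and ends for the same build, without strand, exons or sequence. Each region was therefore assigned to the nearest body of a protein-coding gene within 100 kb, in place of the nearest transcription start that had been planned, which assigned 73249 regions (91.2%), 53.3% of the tested regions lying inside a gene body. Location was classed as within 1 kb of a gene end, inside a gene body or outside. The build was checked: 23.8% of regions called in all libraries lay within 1 kb of a gene end, and 4.48% after shifting positions by 1 Mb. Where several gene bodies covered a region's midpoint, the shortest gene was taken. Motifs, exons and introns were not analysed here. For each gene the called regions assigned to it were counted in each library, and 11212 genes with at least 2 regions were tested.

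All tests are two-sided and were computed in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, with figures by Matplotlib 3.10.9. For genotype and for DHT over all 16 libraries, a region was tested by an exact stratified test (the number of called libraries against its hypergeometric distribution within the other factor) and a gene by an exact permutation test within the other factor (4900 arrangements, smallest p 0.000408), each with Benjamini-Hochberg correction at an adjusted p under 0.05. With 4 libraries against 4 the smallest p is 0.0286, so regions called in all libraries of one group and none of the other were counted and set against the 35 splits of the 8 libraries. For the pooled comparisons 100 label draws with a fixed seed were used. Differences in the DHT effect between genotypes were tested by permuting treatment labels within each genotype, which assumes no DHT effect. For genes and lists this was repeated after subtracting from the DHT libraries the mean DHT effect of both genotypes, a test added after seeing the data, whose p is approximate because that mean is estimated. Chromosome and list shares were tested by exact permutation. Where a p is the smallest possible, no effect size can be ranked by it, so sizes are given as called regions or ratios.

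The analysis used 17 gene lists, in which 276 of 277 entries were matched: androgen response, luminal epithelium, proximal luminal progenitor, secretory prostate, basal epithelium, seminal vesicle and urothelium, neuroendocrine, stromal and smooth muscle, endothelial, immune, SPOP and reported substrates, steroid receptors and partner factors, AP-1 and immediate early, interferon and inflammation, Wnt, Notch and Hedgehog, cell cycle, and housekeeping. For each library the share of its called regions at the genes of a list was computed, with correction over the 17 lists. The rule for named genes takes, for each pooled comparison, the 6 genes per direction with the largest change among those that passed. For each comparison of 4 against 4 it takes the 5 genes per direction with the most separated regions and the 3 separated regions per direction with the highest median within-list percentile of -log10 p. In each list it takes the 3 genes with the smallest p. Always included are, among others, Spop, Foxa1, Hoxb13, Fkbp5, Tmprss2, Pbsn, Krt5, Krt8, Trp63, Ncoa3 and Trim24. A few genes that the rule or the search for values apart from their group takes are not reported here. The groups, comparisons, tests, lists, this rule and the other settings, except those named as added, were chosen before the data were examined. The comparison of shares per chromosome and the assignment to gene bodies were added afterwards.

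Replicate numbers were checked as a pairing: deviations of same-numbered libraries correlated from -0.110 to 0.0973 across regions (24 pairs, mean 0.0160), and the own number correlated best in 21 of 48 pairings, where chance gives 12. All 6 pairs of library 2, the shortest list of each group, correlated above 0. The correlations were weak and the labels state no pairing, so libraries were not treated as paired, and blocked values are given among the other settings. The tests were also run on simulated calls. With 5000 regions called in 95% of libraries of one level and 5% of the other, 81.0% were recovered for genotype and 80.3% for DHT, with 200 such regions or with 80% against 20% none were, and with no change none were called. With 3000 genes changed from 30% to 90% of their regions, 90.9% and 91.0% were recovered for genotype and DHT, with 200 such genes 0 and 51%, and from 50% to 80%, 24.5% and 22.0%. With an equal DHT effect from 30% to 90% in both genotypes 0 genes were called for a difference of DHT effects, and with the effect in SPOPmut only 40.4% of 3000 were recovered. Few or partial changes are therefore often missed by these tests.

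Other settings run were fixed 501 bp windows, a call needing an overlap of at least 0.5 of the peak or of the region, a stricter threshold (-log10 p of at least 3.63), lists of equal length (the strongest 57245 peaks of each), regions called in at least 1 or at least 4 libraries, autosomes only, regions counted over the gene body and 10 kb either side or within 25 kb, shares in place of counts, gene ends within 5 kb, a Jaccard index over regions, a replicate block, and leaving out each library in turn. Added after seeing the data were counts corrected for each chromosome's call rate, leaving out the SPOPmut DHT libraries 3 and 4, leaving out library 2 of every group, leaving out libraries of both genotypes together, a split of the Control EtOH libraries, gene ends compared with other regions called in some of the libraries, and the count of differences where a genotype could not move.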

Results

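Open chromatin was mapped by ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA, in mouse prostate organoids, which are cultures that keep prostate epithelial cell types. The organoids were either Control (described as normal) or mutant for SPOP (SPOPmut). SPOP is the substrate-binding adaptor of a cullin 3 ubiquitin ligase and is recurrently mutated in prostate cancer. Each genotype received 10 nM dihydrotestosterone (DHT), a potent natural androgen, or its solvent ethanol (EtOH) for 24 h, in medium lacking mEGF, a growth factor. This gave 4 groups of 4 libraries. The measurement was whether a genomic region carried one of the authors' peak calls in a library, so the read depth behind a call is unknown and no intervals for counting error can be given. Lists held 62302 ± 3421 peaks in Control with EtOH, 61014 ± 2406 in Control with DHT, 63398 ± 3166 in SPOPmut with EtOH and 64192 ± 4832 in SPOPmut with DHT (mean ± SD, n = 4). None of the 4 differences between groups passed an exact permutation test (smallest p = 0.257, adjusted p = 0.771). The labels do not say whether libraries of a group came from separate cultures or animals, so the p-values measure only the spread between these libraries.

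Libraries of a group resembled each other more than libraries of another group. Over the bases covered, the Jaccard index (shared bases over all covered bases) averaged 0.817 within groups and 0.695 between genotypes in EtOH, and 0.821 against 0.682 in DHT. Between treatments it averaged 0.743 in Control and 0.744 in SPOPmut. Within minus between was 0.122 and 0.139 for genotype and 0.0662 and 0.0842 for treatment. Other splits of the same 8 libraries gave at most 0.0227. Of 80352 regions called in at least 2 libraries, 39300 (48.9%) were called in all 16.

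The first question was how SPOP mutation alters accessible chromatin. At Spop itself (gene 20747, chromosome 11, 95414083 to 95493410, mm10) both genotypes had 6.0 ± 0 called regions in EtOH, and both averaged 7.0 in DHT (SD 0.816 in Control and 0 in SPOPmut, n = 4 each; exact permutation p = 1). The largest rise was at Mecom (gene 14013, chromosome 3, 29951296 to 30509759), which encodes a zinc finger transcription factor: 10.5 ± 1.0 and 11.5 ± 1.73 called regions in Control with EtOH and DHT, and 26.5 ± 1.0 and 29.2 ± 1.26 in SPOPmut. Plcb1 (gene 18795, chromosome 2, 134786164 to 135475258), a phospholipase C gene, rose from 5.25 ± 0.957 to 20.8 ± 0.50 in EtOH and from 4.25 ± 0.50 to 18.5 ± 1.29 in DHT. The largest fall was at Rerg (gene 232441, chromosome 6, 137054825 to 137170496), which encodes a Ras-like protein described as a growth inhibitor. Rerg had 12.5 ± 1.29 and 14.2 ± 0.957 called regions in Control and 0 and 1.0 ± 0 in SPOPmut, with EtOH and DHT in that order. Il15, a cytokine gene on chromosome 8 (gene 16168, 82331624 to 82403252), had 8.0 ± 0 and 9.0 ± 0 called regions in Control and none in any SPOPmut library. Adjacent regions around Il15 were absent together from SPOPmut, as given below, and DNA copy number there was not analysed.

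The other genes with the largest rises in SPOPmut, averaged over treatments, were Cep128 (chromosome 12, by 12.4 called regions), Macrod2 (chromosome 2, by 11.2), Pde4d (chromosome 13, by 9.88), which degrades cyclic AMP, and Ankrd44 (chromosome 1, by 9.0). The other largest falls were at Cachd1 (chromosome 4, -12.6), the zinc transporter gene Slc39a11 (chromosome 11, -11.1), Aopep (chromosome 13, -10.8), the lipid flippase gene Atp10b (chromosome 11, -10.5) and the potassium channel gene Kcnj15 (chromosome 16, -9.62). Each of these 12 genes had an exact permutation p of 0.000408, the smallest the test can give, and an adjusted p of 0.00325, except Aopep (adjusted p = 0.00585). At that smallest p every SPOPmut library lies beyond every Control library of the same treatment. Across the 11212 genes tested, 3527 differed between genotypes at an adjusted p under 0.05, of which 2175 (61.7%) had more called regions in SPOPmut and 1352 fewer. That excess of rises depended on the scaling. As shares of each library's called regions, 4916 genes differed and 51.2% were higher. After subtracting what each chromosome's call rate predicts, a setting chosen after seeing the data, 5500 differed and 48.9% were higher.

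**Figure D1:**
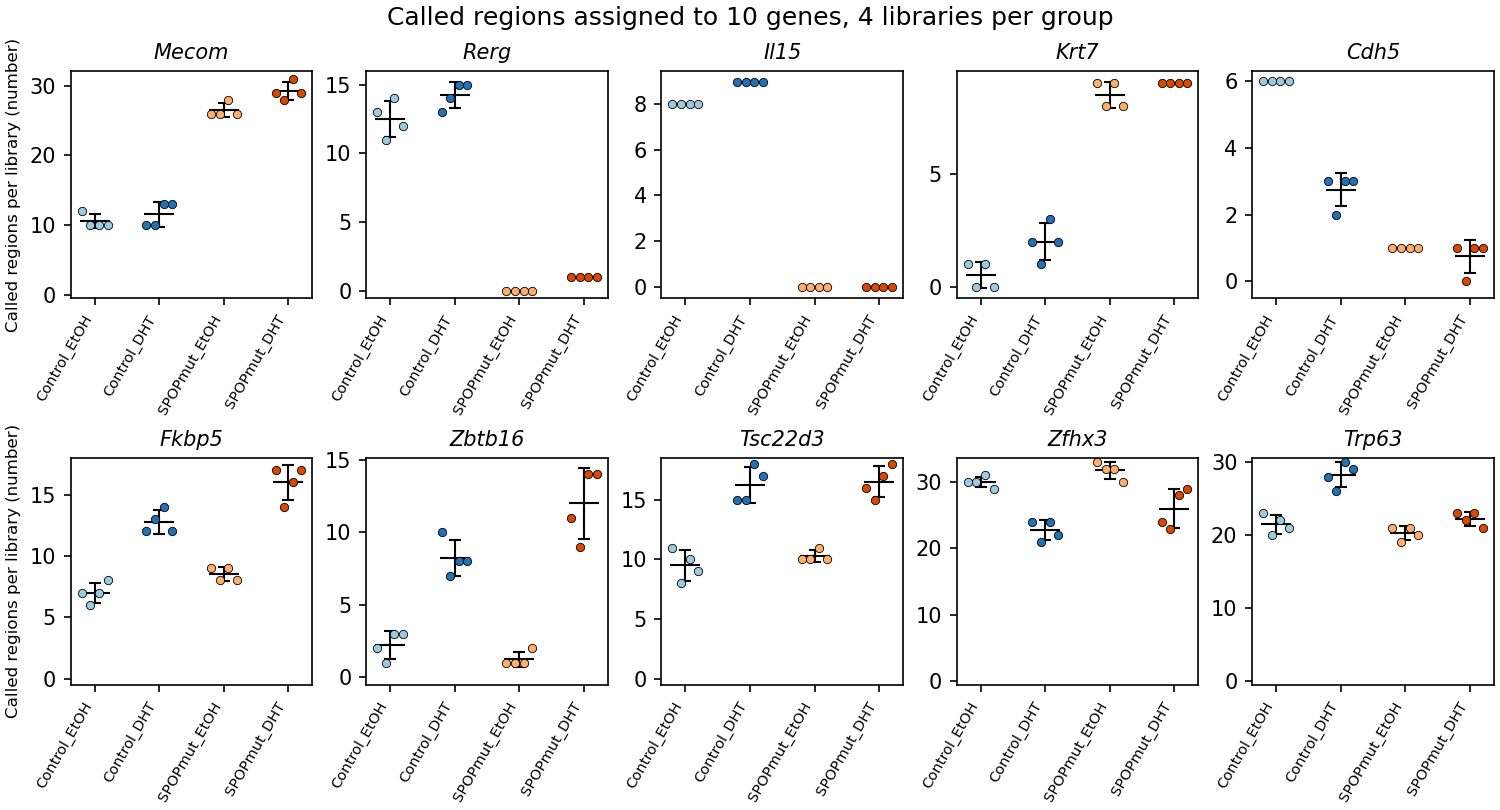
Number of called regions assigned to each of 10 genes (vertical axes) in each of the 16 libraries (points), by genotype and treatment, with the mean ± SD of each group of 4. Rerg has 0 or 1 called regions in every SPOPmut library, and Fkbp5 rises with DHT in both genotypes, from means of 7.0 and 8.50 to 12.8 and 16.

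Called regions were spread over the chromosomes differently in the 2 genotypes, which bears on every gene compared here. Chromosome 2 held 8.42% ± 0.0350 of called regions in SPOPmut and 7.02% ± 0.0512 in Control (n = 8 each), a relative rise of 19.9%. Chromosome 15 rose by 17.6% and chromosome 7 by 8.41%. Chromosome 14 fell by 15.5%, chromosome 13 by 12.5% and chromosome 8 by 8.83%. The share differed on all 21 chromosomes, higher on 10 and lower on 11, by an exact permutation test with adjusted p from 0.000451 to 0.0437 (chromosome 19, -0.815%). With DHT 6 of 21 chromosomes differed, and on the numbered chromosomes and X no share moved by more than 1.75%. Of 124 named genes tested, 99 kept direction and call after the chromosome correction. The Myc call ended (a rise of 1.12 beyond the chromosome's, exact permutation adjusted p = 0.113, against 4.25 uncorrected). The correction uses a single rate per chromosome and does not remove shifts of part of a chromosome. In 10 Mb bins, ranks of regions called in all libraries shifted unevenly. On chromosome 2 the median shift was at most 4.74 percentile points up to position 30000000, and 7.29 to 15.3 beyond it.

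**Figure D2:**
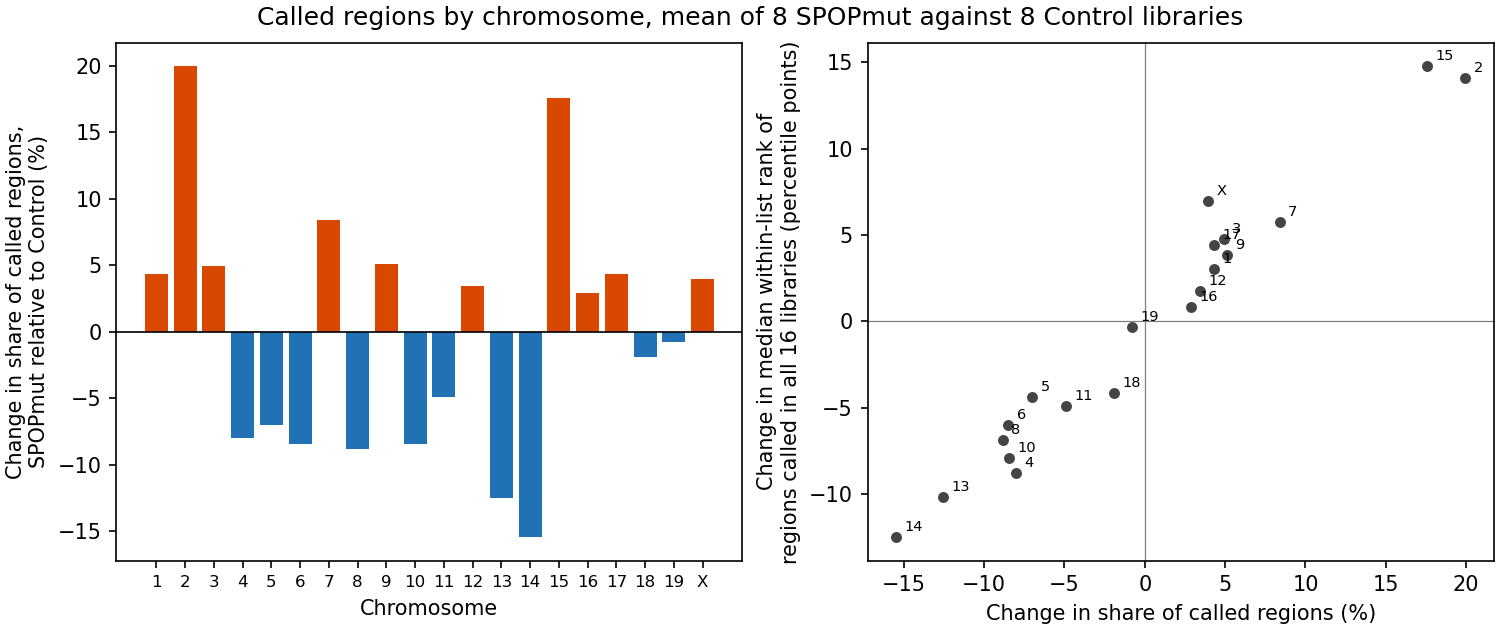
Left, relative change of each chromosome's share of called regions, SPOPmut against Control, in percent (bars). Right, that change against the change of the chromosome's median within-list rank, in percentile points, over the 39300 regions called in all 16 libraries (1 point per chromosome); chromosomes 2 and 15 are highest on both axes and 13 and 14 are low on both.

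Luminal epithelial genes gained called regions in SPOPmut: 6 of 16 tested rose, none fell, 10 did not pass, and adjusted over the list alone the counts were also 6 and 0. The simple-epithelium keratin genes Krt8 (1.0 to 2.75 in EtOH, 1.0 to 2.25 in DHT) and Krt19 (6.25 to 9.0 and 7.0 to 9.0) rose, as did Foxa1 (10.5 to 12 and 9.75 to 12.5), which encodes a pioneer factor that opens closed chromatin (each SD at most 0.957, n = 4). The list took 0.208% ± 0.00397 of called regions in SPOPmut and 0.191% ± 0.00565 in Control (n = 8), higher in 8 of 8 SPOPmut libraries than the mean of Control under the same treatment (exact permutation adjusted p = 0.00173). Krt8 lies on chromosome 15, whose share rose as a whole, and the list still passed after the chromosome correction (exact permutation adjusted p = 0.00297). The Foxa1 call ended when only regions within 25 kb of the gene were counted (a rise of 0.625, exact permutation adjusted p = 0.0812). Rises were not particular to luminal genes. Of 11 housekeeping genes tested 4 rose and 0 fell, and their share rose too, as given below. Of all 11212 genes tested 2175 rose and 1352 fell.

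Genes of the proximal luminal progenitor list, markers of a stem-like luminal state near the urethra, moved apart: 6 of 12 rose and 2 fell, and 7 and 3 adjusted over the list alone. Krt7 rose most, from 0.50 ± 0.577 to 8.50 ± 0.577 in EtOH and from 2.0 ± 0.816 to 9.0 ± 0 in DHT, and Ly6a, which encodes the stem cell antigen Sca-1, rose by 2.0. Both are on chromosome 15. Atp10b fell, as above. The list's share was 1.03 times that of Control (higher in 6 of 8 libraries, exact permutation adjusted p = 0.0463). In EtOH the shares overlapped (0.138% to 0.141% in both genotypes). In DHT they were 0.125% to 0.132% in Control and 0.133% to 0.144% in SPOPmut. The call was lost in 10 of 16 omissions of 1 library, those of each Control DHT library, of Control EtOH libraries 2, 3 and 4, of SPOPmut DHT libraries 1 and 2 and of SPOPmut EtOH library 4 (exact permutation adjusted p from 0.0561 to 0.119). After the chromosome correction the direction turned (-0.00778 in the corrected ratio, exact permutation adjusted p = 0.637). Secretory prostate genes took 1.22 times the share in SPOPmut, in 8 of 8 libraries (exact permutation adjusted p = 0.00578): of 6 tested, Sbp, which encodes spermine binding protein (4.0 to 6.0 in EtOH), and Azgp1 (1.25 to 2.25) rose and 4 did not pass, with the same 2 and 0 adjusted over the list alone. Of 5 seminal vesicle and urothelium genes, only the uroplakin gene Upk1b rose, from 0 in all Control libraries to 2.0 ± 0 in SPOPmut. Adjusted over the list alone 1 rose and 1 fell, and the share was 1.14 times that of Control in 8 of 8 libraries (exact permutation adjusted p = 0.0252, or 0.0503 without Control EtOH library 2).

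Among markers of non-epithelial cells, the endothelial and stromal lists were lower in SPOPmut and the immune list did not pass. Endothelial genes took 0.0515% ± 0.00340 of called regions against 0.0720% ± 0.00233 in Control (n = 8, ratio 0.715, lower in 8 of 8 libraries, exact permutation adjusted p = 0.00173). Of 6 tested, 3 fell and none rose, and 4 fell adjusted over the list alone: Cdh5, which encodes VE-cadherin, went from 6.0 ± 0 to 1.0 ± 0 in EtOH and from 2.75 ± 0.50 to 0.750 ± 0.50 in DHT, and Tek and Erg fell by 1.88 and fell by 1.5. Stromal and smooth muscle genes took 0.83 times the Control share (8 of 8 libraries, exact permutation adjusted p = 0.00278, and 0.229 when regions were counted over the gene body and 10 kb either side). Zeb1 and Dcn fell (by -3.50 and -1.12) and Twist2 rose (by 1.75), 6 did not pass, and the counts adjusted over the list alone were also 1 and 2. The immune list took more (1.14 times, exact permutation adjusted p = 0.0555), though it passed without Control EtOH library 1 or 4 or SPOPmut EtOH library 2 or 4 (exact permutation adjusted p from 0.0319 to 0.0472). Ptprc, which encodes CD45, rose from 4.0 ± 0 to 5.0 ± 0 in EtOH and from 3.25 ± 0.50 to 7.5 ± 0.577 in DHT, and the other 3 tested did not pass (1 and 0 adjusted over the list alone). Neuroendocrine genes did not pass either (0.912 times, 7 of 8 libraries lower, exact permutation adjusted p = 0.0889, but 0.00607 after the chromosome correction, and 0.0451 and 0.0217 without Control EtOH library 4 or SPOPmut EtOH library 3). Foxa2 rose and Ncam1 fell among 5 tested, with the same 1 and 1 adjusted over the list alone.

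Androgen response genes did not differ as a list between genotypes (1.01 times, exact permutation adjusted p = 0.525, but 0.0250 and higher after the chromosome correction). Of 32 tested, 11 rose and 4 fell, and 12 and 5 adjusted over the list alone. Tmprss2 rose from 22 ± 0.816 to 26.8 ± 0.50 in EtOH, Ank rose by 8.38 and Zmiz1, a transcriptional co-regulator gene, fell by 8.88. Among steroid receptors and partner factors 8 of 23 rose and 4 fell (9 and 4 adjusted over the list alone), with 0.992 times the share (exact permutation adjusted p = 0.288). The coactivator gene Ncoa3 rose by 3.25, and Klf4 and Nfia fell by 2.62 and fell by 4.12. Of SPOP and its reported substrates 2 of 14 rose, Ncoa3 and Myc, and Cul3 fell by 0.875 (the same 2 and 1 adjusted over the list alone, 1.02 times the share, exact permutation adjusted p = 0.525). As given above, the Myc call ended after the chromosome correction. Trim24 did not pass, with means of 6.75 and 4.50 in Control and 5.75 and 6.50 in SPOPmut with EtOH and DHT.

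Basal epithelial genes did not differ as a list (1.0 times, exact permutation adjusted p = 0.878). Of 15 tested, 4 rose and 1 fell, also adjusted over the list alone. Itga6, which encodes a laminin receptor subunit, rose by 4.50 on chromosome 2, Trp63, the basal master regulator, fell by 3.62 (exact permutation adjusted p = 0.0180), and Krt5 had 3.0 called regions in every library. The Trp63 fall lay mostly in DHT (26 to 30 called regions in Control libraries, 21 to 23 in SPOPmut). In EtOH the counts overlapped (20 to 23 and 19 to 21). Cell cycle genes took 0.920 times the Control share (8 of 8 libraries, exact permutation adjusted p = 0.00173, but 0.0548 at equal list length). Only the proliferation marker gene Mki67 fell, by 1.75, among 7 tested, also over the list alone. Housekeeping genes took 1.15 times the share (8 of 8 libraries, exact permutation adjusted p = 0.00173). Of 11 tested, 4 rose and none fell, also over the list alone, among them Actb (6.0 ± 0 to 9.0 ± 0 in EtOH). Interferon and inflammation genes took 1.08 times the share (8 of 8 libraries, exact permutation adjusted p = 0.00595). The direction turned when regions were counted over the gene body and 10 kb either side (-0.00340 percentage points). Ccl20 rose by 2.0 and Il6 by 1.25 among 4 of 10 that rose, and 1 fell (4 and 1 adjusted over the list alone). Neither AP-1 and immediate early genes (0.977 times, exact permutation adjusted p = 0.361) nor the Wnt, Notch and Hedgehog genes (0.999 times, exact permutation adjusted p = 0.973) differed. In the first, Dusp1 and Ier3 rose and Fos and Egr2 fell among 13 tested (Egr2 not without Control DHT library 4, exact permutation adjusted p = 0.0774; Fos 0.25 higher when regions were counted over the gene body and 10 kb either side). In the second, 4 of 15 rose, such as Wnt10a by 1.0 and Jag1 by 2.0, and 2 fell, such as Wnt5a by -2.0. Its DHT effect in SPOPmut minus that in Control was -0.0161 percentage points (permutation adjusted p = 0.0729 with the mean DHT effect subtracted). The pooled 0.999 may therefore average unlike genotype differences in EtOH and in DHT. Over each list alone the counts were the same. Several of these calls ended in other settings (exact permutation tests). Over the gene body and 10 kb either side the changes were 0 at Wnt10a, Ier3 and Egr2, 0.50 at Twist2 and Ccl20, 0.375 at Foxa1, -0.50 at Wnt5a, -0.875 at Klf4 and -1.0 at Ncam1 (adjusted p from 0.0896 to 1). Within 25 kb they were 0.375 at Ier3, 0.625 at Twist2 and -1.25 at Ncam1 (exact permutation adjusted p = 0.391, 0.282 and 0.0600), and at equal list length -0.50 at Mki67, -1.0 at Egr2 and -0.875 at Ncam1 (adjusted p = 0.617, 0.0726 and 0.0883). After the chromosome correction Jag1 changed by 0.153 and Ier3 by 0.377 (exact permutation adjusted p = 0.768 and 0.214).

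Compared in EtOH, 7390 regions separated the genotypes completely: 3889 were called in all 4 SPOPmut and no Control library (gained) and 3501 the reverse (lost). In DHT, 5151 were gained and 3388 lost, 8539 in all. Other splits of the same 8 libraries separated at most 164 and 142 regions. Most separated regions were weak calls within their lists. Their median within-list percentile of -log10 p was 23.1 (gained) and 26.6 (lost) in EtOH, and 26.3 and 25.7 in DHT. The single regions named below were picked for the highest percentiles. Plcb1 (12 and 13 in EtOH and DHT) and Mecom (10 and 14) held the most gained regions, followed in EtOH by Lrmda (10), Cep128 (9) and Macrod2 (8) and in DHT by Lhfp (12), Pde4d (12) and the Hippo kinase gene Stk3 (10). Rerg (10 and 12) lost the most, followed in EtOH by Atp10b (10), the retinoic acid receptor gene Rarb (10), Slc39a11 (9) and Aopep (9), and in DHT by Cachd1 (11), Slc39a11 (10), Il15 (9) and Rarb (8). A region in Kcne3 (chromosome 7, 100178186 to 100179255) and a region in Runx2, a bone and epithelial transcription factor gene (chromosome 17, 44542408 to 44543607), were called in all 8 SPOPmut libraries and in no Control library, at within-list percentiles of 88.6 (EtOH) and 90.8 (DHT). A region far from any gene (chromosome 10, 126451992 to 126453547, percentile 96.2) and a region in Clstn2 (chromosome 9, 97603572 to 97604219, percentile 90.7) were called in all 8 Control and no SPOPmut library.

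The 2 treatments shared many genotype regions: 1790 regions were gained and 1623 lost in both, and none moved in opposite directions. Independent sets over all 80352 tested regions would share 249 and 148. The 39300 regions called in all libraries can be in neither set, which makes these expected numbers too low. Over all 16 libraries the exact stratified test called 5614 regions at an adjusted p under 0.05, 3021 gained (53.8%) and 2593 lost. Which direction held the most regions depended on the settings: at equal list length 48.1% of those called were gained, and in EtOH alone 52.6% were gained but 44.9% without Control EtOH library 2, when a loss needed calls in 3 Control libraries. Within 1 kb of a gene end lay 5.68% of gained and 6.68% of lost regions in EtOH, against 6.44% of other regions called in some but not all of the 8 libraries, a comparison chosen after seeing the data (Fisher's exact test, adjusted p = 0.127 and 0.632, or 0.0347 and 0.431 against those called in 4 of the 8; regions are not independent replicates). In DHT the shares were 4.56% and 6.46% against 6.45% (Fisher's exact test, adjusted p = 7.36e-07 and 0.970). Within 5 kb lost regions were fewer, 15.5% against 23.3% in EtOH and 16.9% against 22.8% in DHT (Fisher's exact test, adjusted p = 1.48e-24 and 7.50e-15), and gained regions were 22.4% and 20.8% (adjusted p = 0.26 and 0.00245). As lists, 10 of 17 differed between genotypes in DHT alone, 6 higher and 4 lower, each at the smallest exact permutation p of 0.0286 (adjusted p = 0.0486), and none in EtOH alone. That count fell to 0 in 7 of the 8 omissions of 1 library, all except that of SPOPmut DHT library 1, since at this smallest p at least 10 lists must pass together.

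**Figure D3:**
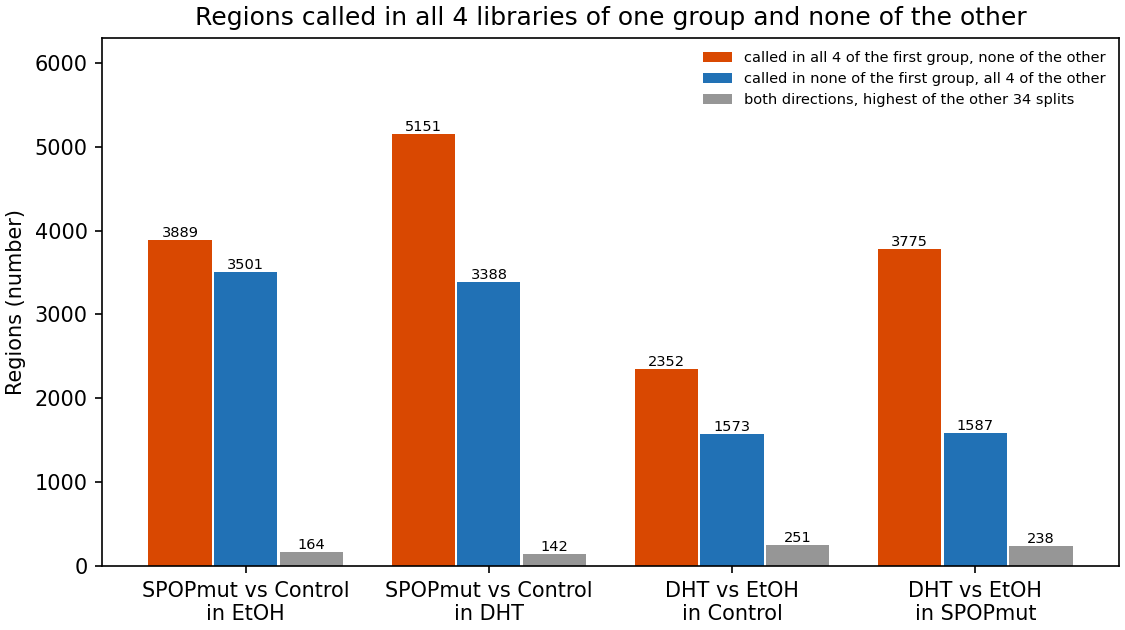
Number of regions (vertical axis) called in all 4 libraries of one group and none of the other, for the 4 comparisons: bars give gained regions, lost regions and the highest total in any other split of the same 8 libraries. Genotype separates 7390 and 8539 regions and DHT 3925 and 5362.

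The second question was the response to androgen. DHT raised called regions most at Zbtb16 (gene 235320, chromosome 9, 48651797 to 48836225), a zinc finger repressor gene and known androgen target, from 2.25 ± 0.957 to 8.25 ± 1.26 in Control and from 1.25 ± 0.50 to 12 ± 2.45 in SPOPmut (n = 4 each). Fkbp5 (gene 14229, chromosome 17, 28398753 to 28486149), which encodes a co-chaperone of steroid receptors, went from 7.0 ± 0.816 to 12.8 ± 0.957 in Control and from 8.50 ± 0.577 to 16 ± 1.41 in SPOPmut. Tsc22d3 (gene 14605, chromosome X, 140539528 to 140600522), a steroid-induced leucine zipper gene, went from 9.50 ± 1.29 to 16.2 ± 1.5 and from 10.2 ± 0.50 to 16.5 ± 1.29. The largest fall was at Zfhx3 (chromosome 8), a homeobox gene, from 30 ± 0.816 to 22.8 ± 1.5 in Control and from 31.8 ± 1.26 to 26 ± 2.94 in SPOPmut. Each had an exact permutation p of 0.000408 (adjusted p = 0.0119), so that each DHT library lay beyond every EtOH library of its genotype.

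Other large rises with DHT were at Fggy (by 8.0), Sox6 (by 7.12), Hsf2bp (by 7.0) and Psd3 (by 6.62), and other large falls at Syne1 (-5.88), Nav2 (-5.62), Inpp4b (-5.12), the estrogen receptor gene Esr1 (-5.0) and Mast4 (-5.0). Of these the adjusted p was 0.0119 except for Fggy and Inpp4b (exact permutation adjusted p = 0.0206) and Nav2 (exact permutation adjusted p = 0.0417). The Nav2 call was lost in 10 of 16 omissions of 1 library, kept only without Control DHT library 3 or 4, Control EtOH library 2, SPOPmut DHT library 4 or SPOPmut EtOH library 2 or 4 (exact permutation adjusted p up to 0.0588). In all, 959 genes differed, 607 higher with DHT and 352 lower. Pbsn, a classic androgen-regulated gene, had no assigned region. Spop rose by 1.0 with DHT (exact permutation adjusted p = 0.0288, but by 0.25, adjusted p = 1, at equal list length). Foxa1 (-0.125), Hoxb13 (1.0, from means of 4.75 and 3.50 in Control and SPOPmut with EtOH), Krt8 (-0.25), Ncoa3 (0.25) and Trim24 (-0.750) did not pass. Without library 2 of every group the smallest p the test can give is 0.005 and no gene or region passed for DHT (exact permutation).

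Androgen response genes took 0.592% ± 0.00917 of called regions with DHT and 0.544% ± 0.00701 with EtOH (n = 8, ratio 1.09, higher in 8 of 8 DHT libraries, exact permutation adjusted p = 0.00694). Of 32 tested, 10 rose and 2 fell (13 and 3 adjusted over the list alone), led by Fkbp5, Zbtb16 and Tsc22d3. Tmprss2 rose by 2.38 (exact permutation adjusted p = 0.0417). That call was lost by counting within 25 kb (0.750, exact permutation adjusted p = 0.857), over the gene body and 10 kb either side (0.875, adjusted p = 0.777) or at equal list length (1.25, adjusted p = 0.250). It was also lost in 10 of 16 omissions of 1 library, kept only without Control DHT or EtOH library 3 or any 1 SPOPmut DHT library (exact permutation adjusted p up to 0.0754). Secretory prostate genes took 1.21 times the share (7 of 8 libraries, exact permutation adjusted p = 0.0254, but 0.0879 over the gene body and 10 kb either side). Of 6 tested only the defensin gene Defb50 rose, from 0.50 ± 0.577 to 2.25 ± 0.957 in Control and from 0.750 ± 0.50 to 3.0 ± 0 in SPOPmut (1 and 0 adjusted over the list alone; exact permutation adjusted p = 0.160 over the gene body and 10 kb either side). Basal genes took 1.05 times the share (7 of 8 libraries, exact permutation adjusted p = 0.0389). Of 15 tested only Trp63 rose (also over the list alone), from 21.5 ± 1.29 to 28.2 ± 1.71 in Control and from 20.2 ± 0.957 to 22.2 ± 0.957 in SPOPmut. The difference between those responses was -4.75 (permutation adjusted p = 0.0774 with the mean DHT effect of both genotypes subtracted first, but 0.0175 within 25 kb and 0.0166, 0.0479 and 0.0346 without Control DHT library 2, Control EtOH library 1 or SPOPmut EtOH library 2).

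Lower with DHT were 4 lists: proximal luminal progenitor genes (0.953 times, 7 of 8 libraries, exact permutation adjusted p = 0.0254), neuroendocrine genes (0.880 times, 7 of 8, adjusted p = 0.0389), Wnt, Notch and Hedgehog genes (0.958 times, 7 of 8, adjusted p = 0.0436) and cell cycle genes (0.969 times, 8 of 8, adjusted p = 0.0405). For Wnt, Notch and Hedgehog genes the DHT effect in SPOPmut minus that in Control was -0.0161 percentage points. That difference did not pass (permutation adjusted p = 0.0729 with the mean DHT effect subtracted), but the pooled fall may not hold alike in both genotypes. The same holds for proximal luminal progenitor genes (0.00799 percentage points, permutation adjusted p = 0.0948 in that test). Their shares in Control were 0.138% to 0.141% with EtOH and 0.125% to 0.132% with DHT. In SPOPmut they overlapped, 0.138% to 0.141% with EtOH and 0.133% to 0.144% with DHT. Proximal luminal and cell cycle genes turned higher when regions were counted over the gene body and 10 kb either side (by 0.00128 and 0.00198 percentage points). Few of their members passed: Runx1 fell by 4.50 among 12 proximal luminal genes, Wnt5a by -1.5 among 15 Wnt, Notch and Hedgehog genes, the cyclin gene Ccnd1 by -1.12 among 7 cell cycle genes, and none of 5 neuroendocrine genes. Adjusted over the list alone, 3 proximal luminal genes rose and 3 fell, and in each of the other lists none rose and 1 fell. These 3 calls ended over the gene body and 10 kb either side (-0.875 at Runx1, -0.25 at Wnt5a and 0 at Ccnd1, exact permutation adjusted p = 0.578, 1 and 1) and within 25 kb (-2.25, -0.50 and 0, exact permutation adjusted p = 0.124, 0.437 and 1). Several list calls with DHT rested on single libraries. The basal call was lost without Control DHT library 4, any 1 Control EtOH library, SPOPmut DHT library 1 or 2 or SPOPmut EtOH library 2 or 3 (exact permutation adjusted p up to 0.0729). The neuroendocrine call was lost without Control DHT library 4, Control EtOH library 2 or 3, SPOPmut DHT library 1 or 2 or SPOPmut EtOH library 1, 2 or 3 (exact permutation adjusted p up to 0.0798). The Wnt, Notch and Hedgehog call was kept only without Control DHT library 1 or 2 or Control EtOH library 3 or 4 (otherwise exact permutation adjusted p up to 0.0952), and the cell cycle call only without Control DHT library 1, 2 or 3 or Control EtOH library 1 or 3 (otherwise up to 0.0892). The proximal luminal call was lost only without Control DHT library 4 (exact permutation adjusted p = 0.0585).

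The other 10 lists did not pass with DHT (exact permutation tests, n = 8 libraries per treatment). Ratios and adjusted p were 1.01 and 0.444 for luminal genes, 1.0 and 0.937 for seminal vesicle and urothelium genes, 0.974 and 0.618 for stromal genes, 0.992 and 0.846 for endothelial genes, and 0.939 and 0.439 for immune genes. They were 1.03 and 0.237 for SPOP and its substrates, 0.999 and 0.867 for steroid receptors and partners, 1.04 and 0.18 for AP-1 genes (0.0468 without Control EtOH library 2), 0.963 and 0.0902 for interferon genes (0.0231 without Control DHT library 2), and 1.01 and 0.553 for housekeeping genes. Single members that rose were Cd24a (luminal, by 1.12, lost without Control DHT library 3 or 4 or Control EtOH library 2, exact permutation adjusted p up to 0.0685), Cldn5 (endothelial, by 1.38), Gli3 and Spop (by 3.25 and 1.0), Fos (by 1.62) and Hprt (by 1.0), and among steroid receptors and partners 3 rose, such as Grhl2 and Tfap2a (by 3.12 and 1.88), and 2 fell, Esr1 and Runx1. No member of the seminal vesicle, stromal, immune or interferon lists passed. Calls ended over the gene body and 10 kb either side at Cd24a and Grhl2 (0.50 and 0.625, exact permutation adjusted p = 0.390 and 0.558), within 25 kb at Cd24a and Gli3 (0.50 and 1.75, adjusted p = 0.342 and 0.0719) and at equal list length at Hprt (0.50, exact permutation adjusted p = 0.127). Adjusted over the list alone the counts of rises and falls were the same except in the luminal (1 and 1), seminal vesicle (1 and 0) and endothelial (1 and 1) lists.

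**Figure D4:**
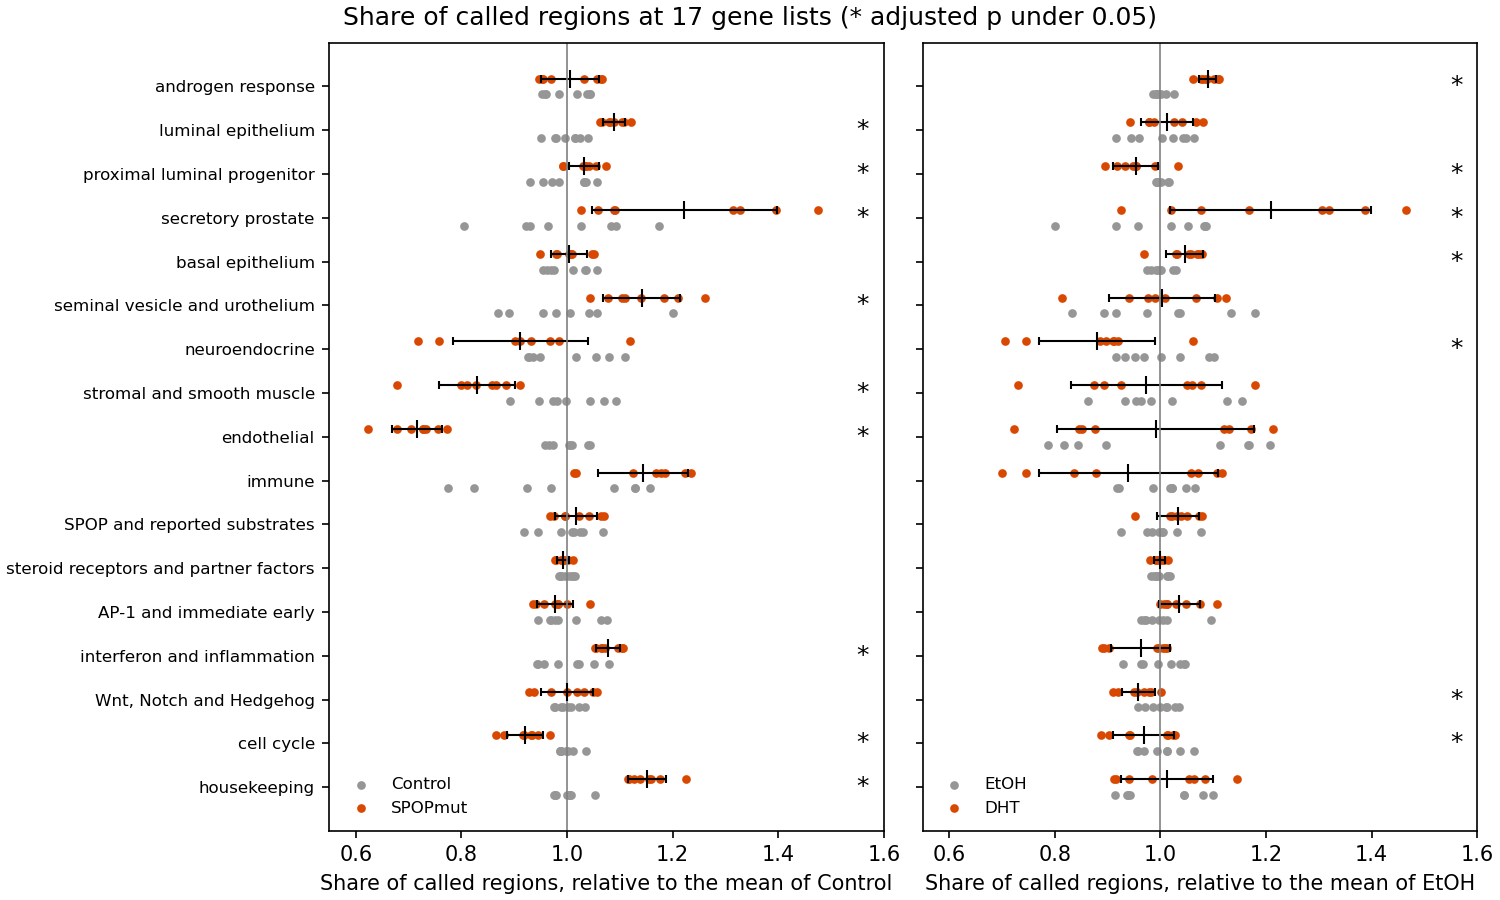
Share of each library's called regions that falls at the genes of each list, relative to the mean of the comparison group (horizontal axis, ratio), for SPOPmut against Control (orange against grey points, 8 libraries each) and for DHT against EtOH. Black bars give the mean and SD of the orange group and an asterisk an adjusted p under 0.05; the endothelial list is lowest in SPOPmut, with a ratio of 0.715, and the androgen response list is higher with DHT, with a ratio of 1.09.

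In Control, 2352 regions were gained with DHT and 1573 lost. In SPOPmut, 3775 were gained and 1587 lost. The most gained regions were at Fggy (7), Hsf2bp (6), Psd3 (6), Sox6 (5) and Cdkal1 (5) in Control, and at Sox6 (9), Lhfp (8), Cdkal1 (8), Zbtb16 (7) and Peli1 (7) in SPOPmut. The most lost regions were at Adgrv1 (5), Zfhx3 (4), Rarb (4), Trim52 (4) and the hyaluronan synthase gene Has2 (3) in Control, and at Gpr158 (5), Lrmda (5), Stard13 (5), Sema3d (4) and Slc39a10 (4) in SPOPmut. Regions in Ilrun (chromosome 17, 27759636 to 27760899, percentile 98) and near Spink4 (chromosome 4, 40886282 to 40887790, percentile 95.8) were called in all 8 DHT libraries and no EtOH library. A region 15930 bp from Igsf3 (chromosome 3, 101360008 to 101361476, percentile 67.8) was called in all 8 EtOH and no DHT library. Other splits of the same 8 libraries separated at most 251 regions in Control and 238 in SPOPmut. Here too most separated regions were weak calls within their lists. The median within-list percentile was 28.9 (gained) and 17.9 (lost) in Control, and 31.2 and 16.4 in SPOPmut.

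Both genotypes gained 1214 regions in common with DHT and lost 208, with none in opposite directions. Independent sets over all tested regions would share 110 and 31.1, numbers too low for the reason given above. Over all 16 libraries the 1422 regions gained or lost in both genotypes, 85.4% of them gained, were the ones the exact stratified test called (smallest adjusted p = 0.0231). Within 1 kb of a gene end lay 3.49% of gained regions in Control and 3.31% in SPOPmut, against 6.15% and 5.93% of other regions called in some but not all of the 8 libraries (Fisher's exact test, adjusted p = 2.02e-07 and 3.18e-10), and 7.43% and 6.84% of those called in 4 of the 8. In Control 59.9% of separated regions were gained, but losses were the more numerous without Control EtOH library 2, the shortest list, when a loss needed calls in 3 EtOH libraries (2367 gained, 2723 lost). In SPOPmut 70.4% were gained, and 53.9% without the DHT libraries 3 and 4, the longest lists of that group, when a loss needed no call in 2 libraries (3878 gained, 3319 lost), an omission chosen after seeing the data.

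The third question was whether the androgen response differs between genotypes, which was tested as the difference of DHT effects. In 4124 regions the share of libraries called changed with DHT by at least 1 more in one genotype than in the other: 2600 responded higher in SPOPmut and 1524 higher in Control. Of the 2600, 1635 were gained by all SPOPmut libraries and 855 were lost by all Control libraries. No permutation tested that count against equal DHT effects in both genotypes, since exchanging treatment labels assumes no DHT effect at all. Without the SPOPmut DHT libraries 3 and 4, when 2 libraries set the share, 47.9% responded higher in SPOPmut. Of the 4124, 2827 had no call in any library of 1 genotype. In 1548 the genotype that moved less could not move that way, having no call to lose or none to gain in EtOH, and of the other 2576, 1831 responded higher in SPOPmut. Of the 3775 regions gained in SPOPmut, 1418 were called in no Control library and 2140 had more calls with DHT than with EtOH in Control. Of the 2352 gained in Control, 367 were called in no SPOPmut library and 1757 had more calls with DHT in SPOPmut. For genes, permuting treatment labels alone found 0 of 11212 (799 at an unadjusted p under 0.05), but a shared DHT response widens that test's own chance range. With the mean DHT effect of both genotypes subtracted first, a test chosen after the data were seen, 573 genes responded differently (permutation adjusted p under 0.05), 407 higher in SPOPmut and 166 higher in Control. In 45 of them the genotype that moved less could not move that way, and of the other 528, 380 were higher in SPOPmut. DHT changed called regions at Lhfp by -1.25 in Control and 8.0 in SPOPmut, from 9.25 ± 0.50 and 12.8 ± 0.50 in EtOH (n = 4, permutation adjusted p = 0.00890). At Sox6, which encodes an HMG-box transcription factor, the changes were 3.75 and 10.5, at the kinase gene Stk3 0.750 and 5.75, and at Peli1, which encodes a ubiquitin ligase, 4.0 and 7.0 (permutation adjusted p = 0.00890 for the last 2 genes). Hsf2bp gained 10 in Control and 4.0 in SPOPmut (permutation adjusted p = 0.0256). The Sox6 call (permutation adjusted p = 0.0407) ended at equal list length (0.144) and without any 1 SPOPmut EtOH library (up to 0.0891), and the Peli1 call over the gene body and 10 kb either side (0.656). Without SPOPmut DHT libraries 3 and 4, 52.3% of 725 genes were higher in SPOPmut, without Control EtOH library 2, 79.2% of 893, and without library 2 of every group no gene passed (smallest possible p = 0.005, permutation). None of the 32 androgen response genes tested was among the 573, and for that list the difference of 0.0155 percentage points did not pass (permutation p = 0.0502, adjusted p = 0.171). Of 17 lists only the immune list did: its share went from 0.0213% ± 0.000537 to 0.0165% ± 0.00170 in Control and from 0.0205% ± 0.00154 to 0.0228% ± 0.000590 in SPOPmut, a difference of 0.00704 percentage points (exact permutation adjusted p = 0.0139, or 0.00694 with the mean effect subtracted). It rests on 18 regions, and the call ended when regions were counted within 25 kb (exact permutation adjusted p = 0.304) or over the gene body and 10 kb either side (0.736), at equal list length (0.0624), within the replicate block (0.133) and without library 2 of every group (0.170).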

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

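Chosen after the results were seen were the tests on the 5 least changed chromosomes, of simulated DHT effects, of DHT effects with their mean subtracted, with a library of each genotype left out, without library 2 of every group and without SPOPmut DHT libraries 3 and 4, while the 35 splits were chosen before and only the bound against chance was written after.

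SPOPmut and Control organoids differed in the share of called regions on all 21 chromosomes. Separate regulation of individual genes is argued against as the whole account, since 94.2% of the 10 Mb bins on these chromosomes moved the chromosome's way in the rank of regions called in all 16 libraries, and unequal list length is argued against by 20 chromosomes that kept their direction at equal list length. A difference in chromosome copy number between the organoid lines stays open: across 20 chromosomes the change in share followed the change in median rank (Spearman rho 0.956), and 94.2% of bins moved together. Read depth and DNA copy number were not analysed here and stay open, and whether such a difference would go with SPOP or with the culture of these lines is untested.

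More regions gained calls with DHT in SPOPmut than in Control (3775 against 2352 gained, ratio 1.61). The tables argue against unequal list length (1.5 at equal list length) and a single library (at the lowest 1.40 without Control DHT library 2, and 1.41 with 1 library of each genotype left out, SPOPmut DHT library 4 and Control DHT library 2). On chromosomes 12, 16, 18, 19 and X, whose shares changed least, the ratio was 1.6. That set does not decide on copy number, which stays open. Median ranks of regions called in all libraries moved there by 6.98 percentile points on X, -4.16 on 18, 1.74 on 12, 0.822 on 16 and -0.316 on 19. Without library 2 of every group the ratio was 1.71. Without SPOPmut DHT libraries 3 and 4 and 2 of the Control DHT libraries it was 1.21 to 1.46, so part of the excess may rest on those long lists. A stronger opening response to androgen in SPOPmut organoids stays open as a hypothesis, as does unequal read depth, which the lists do not hold, and the ratio was not set against other splits.

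Endothelial marker genes had fewer called regions in SPOPmut. Copy number of whole chromosomes is argued against as the whole account, since the list kept an adjusted p of 0.00173 in the exact permutation test with counts corrected for each chromosome. That correction does not remove shifts of part of a chromosome, which stay open. Fewer endothelial cells in the SPOPmut organoids stay open as a candidate source: 8 of the 10 genes had a lower mean over both treatments, none a higher one, and Sox17 and Fli1 had no region. That count covers the same genes whose fall is to be explained, so it cannot tell fewer cells from other sources. It includes Cldn5, which changed by -0.125, and Emcn and Kdr, with 1 region each. Means in Control and SPOPmut with EtOH were 14.2 and 12.2 at Vwf, 10.2 and 10 at Pecam1, 6.50 and 4.75 at Erg, 6.0 and 1.0 at Cdh5 and, the other way, 1.5 and 2.0 at Cldn5. No endothelial gene is on another list, the labels name no sort that would remove such cells, which of these genes prostate epithelium also expresses was not measured here, and a change of these genes within epithelium is untested.

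In 4124 regions the DHT effect differed by at least 1 between genotypes. Random exchanges of treatment labels within genotypes gave as many in 3 of 100 draws, the real labels being 1 of the 3 (highest other 5549, which kept the true labels of SPOPmut and moved 2 in Control), so random labels can be excluded at that share, but they assume no DHT effect and do not test equal effects. Simulated calls with equal DHT effects in both genotypes gave as many in 0 of 100 simulations (highest 639), which rests on an assumed model and excludes nothing. The DHT effect on the immune list differed by 0.00704 percentage points (exact permutation adjusted p = 0.0139, but 0.736 over the gene body and 10 kb either side, 0.304 within 25 kb, 0.0624 at equal list length, 0.133 within the replicate block and 0.170 without library 2 of every group). With the mean DHT effect subtracted, 573 genes differed, and 1 of 100 draws, the real one, gave as many (highest other 130). These draws also exchange treatment labels, so they argue against random labels but do not by themselves test equal effects. The test was added after the planned one found 0 genes, and without library 2 of every group no gene passed. The named genes among the 573, by the change in SPOPmut minus that in Control, were Lhfp (9.25), Sox6 (6.75), Stk3 (5.0), Trim52 (4.0), Has2 (3.25), Ptprc (3.25), Cdh5 (3.0), Peli1 (3.0), Egr2 (1.75), Acta2 (-1.0), Il15 (-1.0), Tek (-1.75) and Hsf2bp (-6.0). No SPOPmut library had a called region at Trim52 or Il15, so the loss that Control showed at Trim52 could not occur there, and Cdh5 had a mean of 1.0 in SPOPmut with EtOH. Over the gene body and 10 kb either side the difference was 0 at Has2, Ptprc, Egr2 and Il15, and the calls of Has2, Cdh5, Acta2, Il15 and Tek ended at equal list length (permutation tests). Within 25 kb 3 of 11 named genes lost the call and 1 gained it. With the chromosome correction 1 of 14 lost it and 1 gained it. For the separated regions 1 of 35 splits, the real one, gave as many, the smallest share these splits can give. The numbers were 7390 for genotype in EtOH (highest other 164), 8539 in DHT (142), 3925 for DHT in Control (251) and 5362 in SPOPmut (238). For the pooled comparisons 1 of 100 draws, the real one, gave as many: 5614 regions and 3527 genes for genotype and 1422 regions and 959 genes for DHT, with 0 in every other draw. Random grouping of these libraries can be excluded at those shares. The splits and draws cannot tell SPOP mutation from other differences between the Control and SPOPmut organoid lines. The labels do not say whether libraries of a group are separate cultures.

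In each group of 4 libraries a value was singled out when its gap to the nearest other exceeded 0.83 of the group's range. Of 434 groups of values 127 held such a value, where chance gives about 1 in 20, or 21.7. That excess arises from ties: in 123 the other 3 libraries had equal counts, which puts the ratio at its maximum whatever the gap. Library 2, the shortest list of each group, had 47 of the 71 low values, and the numbers of high values were 12, 3, 24 and 17 for libraries 1 to 4. Of the shares of called regions, the proximal luminal list had 0.141% in Control EtOH library 1 (0.138% to 0.139% in the others), the neuroendocrine list 0.0384% in Control DHT library 3 (0.0329% to 0.0332%) and the interferon and inflammation list 0.114% in Control DHT library 2 (0.102% to 0.103%).

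Control DHT library 1 had fewer called regions than the other 3 libraries of its group, 7 against 8 at Ccnd1 and 9 against 10 at Foxa1. Control DHT library 1 had more, 8 against 7 at Irf1, 4 against 3 at Pax2 and 5 against 4 at Plcb1. Control DHT library 2 had fewer, 13 against 14 at Ank, 11 against 13 at Ankrd44, 4 against 5 at Ccne1, 2 against 3 at Cdh5, 5 against 6 at Cdk1 and 1 against 2 at Cul3. Control DHT library 2 had fewer, 12 against 14 at Esr1, 1 against 2 at Krt20, 4 against 5 at Neurod1 and 3 against 4 at Upk3b. Control DHT library 3 had fewer, 6 against 7 at Dusp1 and 6 against 8 at Sema3d. Control DHT library 3 had more, 2 against 1 at Bub1, 1 against 0 at Csf1r, 4 against 3 at Dek, 1 against 0 at Foxa2, 5 against 4 at Gpr158, 2 against 1 at Pdgfra and 4 against 3 at Ptprc. Control DHT library 3 had more, 1 against 0 at Spink1, 9 against 8 at Stk3 and 10 against 9 at Wnt5a. Control DHT library 4 had fewer, 2 against 3 at Tek. Control DHT library 4 had more, 4 against 3 at Egr2, 13 against 12 at Itga6, 8 against 7 at Ngfr and 5 against 4 at Sbp. Control EtOH library 1 had more, 6 against 5 at Cdk1, 12 against 10 at Mecom, 5 against 4 at Ncoa3 and 9 against 7 at Stk3. Control EtOH library 2 had fewer, 1 against 2 at Bub1, 2 against 3 at Cd24a, 24 against 31 at Fggy, 4 against 5 at Hoxb13, 9 against 10 at Klf4, 1 against 2 at Krt20 and 12 against 16 at Lrmda. Control EtOH library 2 had fewer, 3 against 4 at Ly6a, 31 against 36 to 37 at Nav2, 24 against 27 at Rarb, 0 against 2 at Spink1, 12 against 15 at Syne1, 3 against 4 at Upk3b and 10 against 11 at Wnt5a. Control EtOH library 2 had more, 3 against 2 at Gusb. Control EtOH library 3 had more, 19 against 17 at Esr1, 1 against 0 at Foxa2 and 10 against 9 at Lhfp. Control EtOH library 4 had fewer, 2 against 3 at Fgl1 and 16 against 17 at Nfia. Control EtOH library 4 had more, 22 against 20 at Gli3, 2 against 1 at Mcm2, 11 against 10 at Pecam1 and 7 against 6 at Twist2.

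SPOPmut DHT library 1 had fewer, 1 against 2 at Il6, 20 against 21 at Lhfp, 7 against 8 at Sema3d, 26 against 27 at Stard13 and 14 against 15 at Tfap2a. SPOPmut DHT library 1 had more, 4 against 3 at Dek and 3 against 2 at Krt8. SPOPmut DHT library 2 had fewer, 8 against 9 at Actb, 4 against 5 at Ccne1, 0 against 1 at Cdh5, 4 against 5 at Cdk1, 2 against 3 at Cldn5 and 4 against 5 at Erg. SPOPmut DHT library 2 had fewer, 7 against 9 at Irf1, 3 against 4 at Krt4, 1 against 2 at Pax2 and 9 against 11 at Pecam1. SPOPmut DHT library 2 had more, 8 against 7 at Wnt5a. SPOPmut DHT library 3 had fewer, 7 against 8 at Ncoa3. SPOPmut DHT library 3 had more, 4 against 3 at Fgl1, 7 against 6 at Gpr158, 3 against 2 at Gusb and 3 against 2 at Krt20. SPOPmut DHT library 4 had more, 3 against 2 at Atp10b, 9 against 8 at Ccl20, 2 against 1 at Foxa2, 2 against 1 at Mcm2 and 6 against 5 at Mki67. SPOPmut EtOH library 1 had fewer, 8 against 9 at Wnt5a. SPOPmut EtOH library 1 had more, 1 against 0 at Dcn and 12 against 11 at Sema3d. SPOPmut EtOH library 2 had fewer, 1 against 2 at Bub1, 1 against 2 at Cd3e, 5 against 6 at Il1b, 2 against 3 at Krt8, 5 against 6 at Ly6a, 18 against 20 at Myc and 20 against 21 at Plcb1. SPOPmut EtOH library 2 had fewer, 25 against 28 at Slc39a11, 6 against 7 at Sox2 and 15 against 16 at Syne1. SPOPmut EtOH library 3 had fewer, 20 against 21 at Esr1. SPOPmut EtOH library 3 had more, 6 against 5 at Cdk1, 3 against 2 at Krt20, 28 against 26 at Mecom, 8 against 7 at Ngfr, 7 against 6 at Tcf7 and 11 against 10 at Tsc22d3. SPOPmut EtOH library 4 had fewer, 7 against 8 at Cxcl1, 0 against 1 at Defb50, 2 against 3 at Fgl1, 2 against 3 at Il6, 12 against 13 at Lhfp and 24 against 25 at Psd3. SPOPmut EtOH library 4 had fewer, 26 against 27 at Tmprss2 and 5 against 6 at Trim24. SPOPmut EtOH library 4 had more, 2 against 1 at Dek, 1 against 0 at Spink1, 2 against 1 at Zbtb16 and 2 against 1 at Zeb1.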

How the results depend on the processing

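Chosen after the data were seen were the chromosome correction, the omission of SPOPmut DHT libraries 3 and 4, the omission of library 2 of every group, the split of Control EtOH libraries, the gene ends of other regions called in some of the libraries compared and every setting of the test of DHT effects with their mean subtracted.

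The separated regions of the 4 comparisons and the differing genes for genotype stayed within 1.5 times their number under fixed windows, overlap of at least 0.5, the stricter threshold, equal list length and regions called in at least 1 or 4 libraries or on autosomes, where each was run, and when 1 library was left out. With 1 library left out the ranges were 7796 to 8764 regions for genotype in EtOH, 8943 to 9822 in DHT, 4210 to 5090 for DHT in Control, 5621 to 6197 in SPOPmut, 4251 to 4862 for the difference of DHT effects in regions, 3530 to 3720 genes for genotype, 939 to 1072 for DHT and 669 to 893 for the difference of DHT effects with their mean subtracted (893 without Control EtOH library 2). Lists differing ranged from 2 to 8 for DHT (2 without Control DHT library 4, 3 without SPOPmut DHT library 1 or 2 or SPOPmut EtOH library 2 or 3, 4 without Control EtOH library 2 or SPOPmut EtOH library 1), from 0 to 10 for genotype in DHT and from 7 to 10 for genotype. Few or partial changes limit the tests, and what read depth limits is unknown because the lists hold no counts. Motif analyses, with a background matched on GC content and with windows of 50 bp, were not run.

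Leaving out library 2 of every group, 0 regions passed for genotype (smallest adjusted p 0.0910, 7334 at an unadjusted p under 0.05) and 0 for DHT (0.225 and 3131, exact stratified tests), 1881 genes for genotype (1871 of them also with all libraries), 0 genes for DHT, 0 genes for the difference of DHT effects and 0 lists for genotype in DHT, and the difference of DHT effects in regions rose to 6384. Of the 17 lists, 2 lost the call for genotype, and for DHT 4 lost it and 3 gained it. Fewer libraries raise the smallest p to 0.005 and make complete differences easier. Within the replicate block, whose smallest p is 0.00781, 0 regions passed for genotype and 0 for DHT (smallest adjusted p 0.184 and 0.441), 1838 genes for genotype (1832 shared), 0 genes for DHT, 3 lists for DHT and 0 for genotype in DHT; the labels state no pairing. Leaving out SPOPmut DHT libraries 3 and 4 gave 3630 regions for genotype, 534 genes and 3 lists for DHT and 0 lists for genotype in DHT, with 2 fewer libraries. With shares in place of counts 2306 genes differed with DHT (958 shared) and 928 in their DHT effects (545 shared), and with the chromosome correction 926 in their DHT effects (552 shared), 2394 with DHT (958 shared) and 5500 for genotype (3163 shared in direction, 3 opposite); the cause was not tested. Over the gene body and 10 kb either side 2 lists differed with DHT and 0 for genotype in DHT, and within 25 kb 4 with DHT. For genotype, 3 of 17 lists lost the call over the gene body and 10 kb either side, 3 gained it and 1 turned. Within 25 kb 1 list lost the genotype call and 2 gained it. The cause of these changes was not tested.

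Directions turned in 24 values, and the cause was not tested except for gene ends. For genotype with the chromosome correction these were Aldh1a3 (-0.120), Ccnd1 (-0.650), Dpp4 (-0.981), Grhl2 (-1.43), Has2 (-0.116), Notch1 (-1.19) and the proximal luminal progenitor list (-0.00778). Over the gene body and 10 kb either side they were, for genotype, Fos (0.25), Tfap2a (-0.25) and the interferon and inflammation list (-0.00340), and, for DHT, the proximal luminal progenitor list (0.00128) and the cell cycle list (0.00198). Within 25 kb they were Fos (0.125) and Tfap2a (-0.25) for genotype and Trim24 (1.5) and the cell cycle list (0.00109) for DHT, and at equal list length Aopep for DHT (-2.38). Against other regions called in some of the libraries compared, which leaves out by construction those called in all, the share within 1 kb of a gene end was no longer lower for regions lost in SPOPmut in EtOH (6.68%) and DHT (6.46%) or pooled gained (5.86%). For pooled lost regions that share turned higher (7.94%, Fisher's exact test, adjusted p = 7.23e-06). Pooled gained regions were no longer more often outside gene bodies (46.0%). The difference ended near gene ends for genotype gained in EtOH (5.68%) and DHT pooled lost (3.37%), and outside gene bodies for genotype gained in EtOH (47.3%) and DHT (47.3%), genotype pooled lost (49.5%), and DHT gained in SPOPmut (48.5%) and pooled (49.3%). Within 5 kb, against the same other regions, lost regions were fewer near gene ends in every comparison (pooled genotype 17.6% against 21%), pooled gained regions turned to more near gene ends (24.0%) and fewer outside gene bodies (38.3%), and the difference ended for genotype gained in EtOH near gene ends (22.4%) and outside gene bodies (39.5%), and outside gene bodies for genotype gained in DHT (40.0%) and DHT pooled gained (42.8%). Of 124 named genes tested, 99 kept direction and call for genotype with the chromosome correction (6 lost the call, 13 gained it), and without library 2 of every group 19 lost it for genotype and 35 for DHT. The share of separated regions that were gained ranged from 44.9% to 56.0% for genotype in EtOH, 51.7% to 65.2% in DHT, 46.5% to 63% for DHT in Control and 53.9% to 73.7% in SPOPmut.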

Other observations

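Chosen after the values were seen were the search for runs of adjacent regions and the overlap of region sets.

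Of the regions called in all 8 SPOPmut and no Control library 291 (16.3%) lay beside another of the set, and of the reverse 343 (21.1%), against at most 132 and 116 in 100 shuffled orders of the regions not called in every library. Among the 1623 regions called in all 8 Control and no SPOPmut library, 9 neighbours in a row spanned 419 kb around the cytokine gene Il15 and Zfp330 (chromosome 8, 82260189 to 82679478). Runs of 5 covered 818 kb around Vegfc, which encodes a lymphatic growth factor, with Spcs3, Neil3 and Gm33153 (chromosome 8, 53607148 to 54425351), the semaphorin gene Sema3a (chromosome 5, 13012509 to 13478032) and Clstn2 (chromosome 9, 97603572 to 97679771), and a run of 6 lay away from protein-coding genes on chromosome 10 (84060681 to 84101666). Among the 1790 regions called in all 8 SPOPmut and no Control library, the longest run was 6 at Adam28, a metalloprotease gene (chromosome 14, 68646850 to 68696300). The longest run in 100 shuffled orders was 4. DNA copy number of these stretches was not analysed. Local DNA differences between the Control and SPOPmut organoid lines therefore cannot be told apart from changes in chromatin.

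Single regions marked further genes. Lost in all 8 SPOPmut libraries were a region in the potassium channel partner gene Kcnip1 (chromosome 11, 33882635 to 33883275) and a region 5810 bp from the homeobox gene Irx2 (chromosome 13, 72639281 to 72640731). Called in all 8 SPOPmut libraries were a region 75 bp from Plac8 (chromosome 5, 100571841 to 100572814), also called in 1 Control library with DHT, and a region in the transporter gene Abcc5 (chromosome 16, 20413653 to 20415041), also called in 3 Control libraries with EtOH. DHT brought calls in all 8 libraries, with none in EtOH, in the sulfotransferase gene Sult1d1 (chromosome 5, 87562453 to 87563725), in Hpcal1 (chromosome 12, 17723736 to 17725088) and in Aldh6a1 (chromosome 12, 84442548 to 84443542). A region 85998 bp from Amigo2 (chromosome 15, 97157836 to 97158315) was called only in the 4 SPOPmut libraries with EtOH.

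Of the 1573 regions lost with DHT in Control, 529 were also called in no SPOPmut library with EtOH, and 225 of the 2352 gained with DHT were also called in every SPOPmut library with EtOH. Both comparisons share the Control EtOH libraries, which makes such overlap larger by itself. Splitting these libraries between the comparisons leaves both numbers as they are by construction, so the overlap was not tested.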
